A study of Arabidopsis thaliana with 24 samples.

How the data were processed

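Total RNA of Arabidopsis thaliana Col-0 wild type was hybridised to 24 Affymetrix ATH1 arrays. Per the labels, the samples are the vegetative part of seedlings at growth stage 1.03 and leaf 3 at 3 harvests: proliferating on day 9 (leaf area 0.1 mm2), expanding on day 15 (7 mm2) and mature on day 22 (40 mm2). The labels give no day for the seedlings, so their place in time relative to the leaf harvests is not stated. Plants grew in vitro on medium with 0 mM or 25 mM mannitol, a sugar alcohol that lowers the water potential of the medium. Each of the 8 groups has 3 arrays. Per the series' own design text the replicates are independent experiments, and each sample pools many plants, so the array is the unit of replication. The treatment field of the labels names mannitol for every sample, control samples included; samples were grouped by title and by the stress field, which give control or mannitol for each. The number of arrays limits the precision of every value.

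The deposited values are log2 expression levels, 1 per locus and array. Per the submitters' processing notes they come from RMA; its version, the grouping of probes into loci and whether all arrays were processed in a single run are not given in the sources used here. That the scale is log2 was read from the values, which run from 2.52 to 14.4. No background correction or normalization was added. The table held 20777 loci, and all were tested. The reference gene table (assembly TAIR10.1) named 20508 of them; the other 269 keep their locus code, and no coordinates are printed. With 1 value per locus, the comparison of several probe sets of a gene was not run, and whether a value rests on probes that match several genes cannot be read from the table. The planned check of RNA quality from 3' and 5' control probe sets was not run either, since 0 of the loci are such controls.

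Array medians ran from 5.91 to 6.16, the correlation between arrays of a group from 0.990 to 0.997, and the SD of the difference between 2 replicates from 0.176 to 0.325. No 2 arrays held identical values (0 pairs). Control and mannitol arrays were compared on their median and interquartile range with an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. Proliferating leaf (medians 6.12 and 6.15) and mature leaf (5.93 and 5.97) reached it with medians higher under mannitol, and both had a wider interquartile range under mannitol (3.85 and 3.91 in proliferating leaf; 3.67 and 3.75 in mature leaf; exact p 0.1 each). For seedlings and expanding leaves the exact p lay between 0.5 and 1 for both measures.

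Tests were run in R 4.3.3 with limma 3.58.1. A model with 8 group means was fitted to all 24 arrays (lmFit, eBayes; prior SD 0.137 with 6.02 prior degrees of freedom), so that all groups share the estimate of the spread. Contrasts were mannitol minus control at each of the 4 stages, the difference of that effect between each pair of leaf stages, a moderated F test with 2 degrees of freedom of equal effects over the 3 leaf stages, and, between control leaves, expanding minus proliferating and mature minus expanding. Tests were two-sided, and p was adjusted by Benjamini and Hochberg over all 20777 genes within a contrast; a gene was called at an adjusted p under 0.05. Differences between stages are given as the later minus the earlier stage. Overlap of calls between stages was tested with Fisher's exact test, one-sided for more overlap, per direction.

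The contrasts, tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. For each mannitol effect, the rule names the 8 largest rises and 8 largest falls among called genes whose 3 mannitol values all lie on the same side of the 3 control values. It adds up to 4 members with the smallest p from each list, the 5 largest rises and falls of each development contrast, the 8 smallest p of the F test, and a panel of 14 stress and growth genes at every stage, of which 12 were measured (P5CS1 and CDKB1;1 were not). Of 35 lists fixed, 33 were tested. They cover hormones (abscisic acid, ethylene, gibberellin, jasmonate, salicylate, auxin, cytokinin), stress (ERF, WRKY and ZAT transcription factors, alternative respiration, reactive oxygen scavenging, heat shock, proline, raffinose and trehalose, iron), growth (mitotic cell cycle, DNA replication, endocycle, leaf growth regulators, expansins and XTH, aquaporins), metabolism (photosynthesis, flavonoids, glucosinolates), senescence, the circadian clock, the plastid and mitochondrial genomes, and cell type markers (stomatal lineage, guard cell, meristem, root, vascular tissue, trichome). The cytosolic ribosome list found 6 members by description, fewer than the minimum of 10, and the respiratory chain list found 0, so neither was tested. Of 551 list memberships, 503 had a measured locus and 48 had none.

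Lists were tested with camera at its preset correlation of 0.01, two-sided and adjusted over the lists within a contrast. An estimated correlation, fry and a model with the replicate number as a block were alternatives. Counts of members are given over all genes tested and adjusted over the list alone.

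Whether the replicate numbers pair control and mannitol arrays was checked from the correlation of their deviations from the group means, over all genes. It was 0.43, 0.32 and 0.18 in seedlings, 0.27, 0.33 and 0.27 in proliferating leaf and 0.12, 0.21 and 0.16 in expanding leaf, all above the limit of 0.1 set for pairing, so at these stages the blocked value is printed where it changes the call of a list or named gene or moves a printed count by over 1.5 times. Across stages the mean correlation of arrays with the same number was 0.11 for seedlings and expanding leaf (-0.055 for arrays with other numbers) and between -0.099 and 0.045 for the other pairs of stages; no block across stages was used.

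Alternatives were a fit of the compared stages alone, the replicate block, an intensity trend of the prior, leaving out genes whose highest group mean lies below the 40th percentile of all values (14071 genes kept), quantile normalization, centring each array on its median, array weights, a fold minimum of 2, and leaving out each array in turn. The procedure was tested on simulated data with known changes in 20777 genes. Changes of 1.5-fold were recovered for 76.1% of genes in seedlings, 82.1% in proliferating leaf, 71.6% in expanding leaf and 76.1% in mature leaf. Changes of 2-fold were recovered for 97.0%, 95.5%, 98.5% and 98.5%, in the same order. False calls were 10 of 192, 11 of 196, 9 of 189 and 16 of 199. The simulated F test recovered 197 of 197 genes with a 4-fold change, with 32 false calls among 522. A simulated list of 20 genes shifted by 0.30 in expanding leaf had a camera p of 1.43e-14, and 0 of 100 unshifted lists had a p under 0.05. The simulated values were drawn independently for each gene and array. These simulations therefore hold no correlation between genes and no pairing of replicates. They cannot show how many false calls arise in data that have both.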

Results

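Transcript levels were measured on 24 arrays, with 3 control and 3 mannitol arrays at each of 4 stages of the Arabidopsis shoot. The stages were whole seedling shoots and leaf 3 while its cells proliferated, expanded or were mature. The question was whether the response to a mild, lasting osmotic stress differs with the developmental stage of the leaf. Array medians lay between 5.91 and 6.16 on the log2 scale. Unless stated otherwise, a value in parentheses after a gene is its log2 change, mannitol minus control.

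Control leaves were compared first, to set the stage labels against known markers of leaf growth. From proliferating to expanding leaf, cell division genes fell: 19 of 20 mitotic genes (median -3.29; B-type cyclin CYCB1;1, AT4G37490, -4.09; cytokinesis syntaxin KN, AT1G08560, -3.97) and all 16 DNA replication genes (median -2.79; replication clamp PCNA1, AT1G07370, -3.56). Of 18 leaf growth regulators, 14 fell, among them the growth promoters AN3 (AT5G28640, -4.68) and ANT (AT4G37750, -4.44), and 2 rose. All 35 nuclear photosynthesis genes rose (median 1.31), as did all 14 glucosinolate synthesis genes (median 2.55) and all 10 vascular markers (median 2.44; sucrose transporter SUC2, AT1G22710, 5.25). Of 73 plastid genome transcripts, 53 rose and 5 fell (55 and 5 adjusted over the list alone), with a median of 0.61; for the other lists of this paragraph the counts adjusted over the list alone were the same. The largest single changes were the rise of AT1G66100 (8.05, adjusted p = 2.54e-21), followed by AT1G22690 (6.82), AT1G23130 (6.62), GASA6 (AT1G74670, 6.62) and the sucrose phosphate synthase ATSPS4F (AT4G10120, 6.56). The deepest falls were those of AT4G22490 (-8.15), the cutinase CDEF1 (AT4G30140, -7.92), the lipid transfer protein LTP2 (AT2G38530, -7.49), AT5G01870 (-7.12) and AT4G29030 (-6.99). In total 12585 genes differed, 6048 higher and 6537 lower in expanding leaf. The camera adjusted p was 1.19e-12 for the mitotic list, 1.15e-10 for DNA replication, 6.56e-05 for growth regulators, 1.28e-16 for photosynthesis, 1.18e-06 for glucosinolates, 5.72e-06 for vascular markers and 4.65e-08 for the plastid genome. With an estimated correlation only the growth regulators kept the call (adjusted p = 0.035); the others had adjusted p = 0.073 (mitotic, replication and vascular), 0.155 (photosynthesis), 0.157 (glucosinolates) and 0.267 (plastid genome). Centring each array on its median shifted the median change of all genes in this comparison by 0.10, and every list median given here is larger than that shift.

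From expanding to mature control leaf, genes of water deficit, sugar storage and ageing rose. Of 27 abscisic acid and dehydration genes 22 rose (median 1.59; homeobox gene HB-7, AT2G46680, 3.28), of 11 raffinose and trehalose genes 9 rose and 1 fell (median 1.24), and of 16 senescence genes 10 rose (median 0.88; NAP, AT1G69490, 3.82). Adjusted over the list alone these counts were 22 with 1 fall, 9 with 1 fall, and 11. DNA replication fell further, for 15 of 16 genes (median -1.08), with 10 of 20 mitotic genes (median -0.51; 1 rose) and 10 of 13 stomatal lineage genes (median -0.73; SPCH, AT5G53210, -2.45), the same counts adjusted over the list alone. Transcripts of the mitochondrial genome rose, 17 of 31 in either adjustment, with a median of 0.38. The largest rises were galactinol synthase GOLS2 (AT1G56600, 5.50), AT3G62550 (4.83), the senescence gene SEN1 (AT4G35770, 4.47), the linker histone HIS1-3 (AT2G18050, 4.08) and SIP2 (AT3G57520, 3.99). The largest falls were LTL1 (AT3G04290, -6.82), GER3 (AT5G20630, -6.67), AT5G45670 (-5.79), AT1G10640 (-4.84) and AT4G28780 (-4.74). The camera adjusted p was 4.24e-13 for abscisic acid, 5.34e-05 for raffinose, 1.26e-05 for senescence, 3.84e-05 for the mitochondrial genome, 1.17e-05 for stomatal lineage, 3.98e-09 for replication and 0.00127 for the mitotic list. With an estimated correlation these were adjusted p = 0.0463, 0.00943, 0.00943, 0.0463, 0.0463, 0.0746 and 0.437, so the calls of the replication and mitotic lists were lost. In total 8397 genes differed, of which 3904 rose (46.5%) and 4493 fell. After centring each array on its median, 5164 rose (58.4%) and 3672 fell.

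In seedling shoots, rises with mannitol outnumbered falls, and the chitinase family gene AT2G43620 rose most, from 4.23 ± 0.255 to 9.62 ± 0.162 (SD, n = 3; log2 change 5.40 ± 0.252 SE, adjusted p = 3.19e-12). Next came AT1G65500 (4.91), the pectin methylesterase ATPMEPCRB (AT4G02330, 4.68), the chitinase family gene AT2G43590 (3.99), the natriuretic peptide PNP-A (AT2G18660, 3.94), the thaumatin-like defence protein PR5 (AT1G75040, 3.44), the receptor-like kinase CRK14 (AT4G23220, 3.302) and COBL5 (AT5G60950, 3.02), with adjusted p between 1.13e-12 and 0.00014. The falls were smaller. The gibberellin-regulated gene GASA1 (AT1G75750) fell by 1.13 (adjusted p = 1.83e-05), and AT2G38300 (-1.03), AT1G33930 (-1.02), the wall enzymes XTH6 (AT5G65730, -1.05) and XTH17 (AT1G65310, -1.004), the endoglucanase-like GH9B8 (AT2G32990, -0.95), AT5G03120 (-0.94) and AT1G12570 (-0.91) fell with adjusted p up to 0.0294. Of the expansin and XTH list, 3 of 38 fell (XTH6, XTH17 and XTH4, AT2G06850, -0.71) and 2 rose, 4 and 2 adjusted over the list alone, and 5 and 2 with the replicate block. The list test gave adjusted p = 0.1, and 0.0291 with the block. Of its 2 rises, 0 were left without control replicate 1 or mannitol replicate 2, and 1 without control replicate 2 or 3 or mannitol replicate 3. The control level of AT2G43620 lies below 5.11, the level used here for dim genes. So do those given below for AT1G65500 in proliferating leaf, LTP2 in expanding and mature leaf and LTP3 in mature leaf. The control arrays of ERF5 in seedlings and expanding leaf also lie below it (3.82 to 4.45), and other dim genes are not marked. The size of such a change depends on the background correction.

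Glucosinolate synthesis was the seedling list with the smallest p. Of 14 glucosinolate synthesis genes, 3 rose (8 adjusted over the list alone; median 0.52, camera adjusted p = 8.51e-15), among them CYP79B2 (AT4G39950, 1.49) and CYP83B1 (AT4G31500, 0.86). Of 20 stress ERF, WRKY and ZAT transcription factors, 4 rose (4 adjusted over the list alone; median 0.22, adjusted p = 6.87e-07), with WRKY33 (AT2G38470, 1.31) ahead. Marker genes of stomata were lower: the stomatal lineage list had a median of -0.25 (0 of 13 fell, 2 adjusted over the list alone; adjusted p = 9.82e-06), and of 6 guard cell genes the transcription factor MYB60 (AT1G08810, -0.90) and the potassium channel KAT1 (AT5G46240, -0.77) fell (3 adjusted over the list alone; median -0.27, adjusted p = 0.000558). These 4 list calls held with an estimated correlation (adjusted p = 0.0445 each). Further calls did not hold with it. The salicylate list had 4 of 19 rises including PR5 and the camalexin enzyme CYP71A13 (AT2G30770, 2.08), also 4 adjusted over the list alone, with a median of 0.06 (adjusted p = 0.00111, and adjusted p = 0.436 with an estimated correlation). Abscisic acid had 1 of 27, the dehydration gene RD22 (AT5G25610, 0.87), and 1 adjusted over the list alone (median 0.13, adjusted p = 0.00447, and adjusted p = 0.476 with an estimated correlation). Alternative respiration had 0 of 23, but 5 adjusted over the list alone (median 0.08, adjusted p = 0.0145, and adjusted p = 0.134 with an estimated correlation). Senescence had 2 of 16, and 3 adjusted over the list alone (median 0.14, adjusted p = 0.0436, and adjusted p = 0.213 with an estimated correlation). Aquaporins had a lower median (-0.08; 0 of 14 fell, 1 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.213 with an estimated correlation). So did trichome markers (-0.26; 0 of 8, 1 adjusted over the list alone; adjusted p = 0.00341, and adjusted p = 0.253 with an estimated correlation). With the replicate block, 8 glucosinolate and 3 alternative respiration genes rose, and 2 stomatal lineage, 1 aquaporin and 1 trichome gene fell. With single arrays left out, the stress factor count of 4 was 2 without control replicate 1 or mannitol replicate 1, 2 or 3, and 1 without control replicate 3. The salicylate count of 4 was 2 without any 1 of the 6 arrays. The senescence count of 2 was 1 without control replicate 1 or 2, and 0 without control replicate 3 or mannitol replicate 2 or 3. The abscisic acid count of 1 was 2 without control replicate 2. A count of 0 became 1 for alternative respiration without mannitol replicate 3, for stomatal lineage without control replicate 2, and for aquaporins and trichome markers without mannitol replicate 1.

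In the seedling panel, ERF5 (AT5G47230, 0.71, adjusted p = 0.0322) passed the test. The others did not. They were alternative oxidase AOX1A (AT3G22370, 0.07), NADH dehydrogenase NDB2 (AT4G05020, 0.51), RD29A (AT5G52310, 0.17), RAB18 (AT5G66400, -0.59), ERF6 (AT4G17490, 0.21), GA2OX6 (AT1G02400, 0.15), CYCB1;1 (-0.05), EXPA10 (AT1G26770, 0.05), chalcone synthase TT4 (AT5G13930, -0.12), PDF1.2 (AT5G44420, 0.83) and PR1 (AT2G14610, 0.26), with adjusted p from 0.267 to 0.994. In total 301 genes were called in seedlings, 244 higher and 57 lower with mannitol; 300 of them had no overlap between the groups. Chance gives this for 10% of genes without selection; called genes are selected for groups that lie apart, here and at the other stages. At a change of 2-fold or more there were 112 rises and 5 falls. With the replicate block 492 were called (364 and 128), and without mannitol replicate 3 there were 185. Among the genes named here, omission of mannitol replicate 2 ended the call of XTH6 (adjusted p = 0.0611, range over 13 alternatives 0.00012 to 0.0611). The fit of the stage alone ended that of AT1G12570 (0.0873, range 6.51e-05 to 0.0873), and omission of any single array or quantile normalization that of ERF5 (0.0576 to 0.169, range 0.00273 to 0.169). The block ended that of AT5G03120 (0.0547), which also failed without control replicate 2 or 3 or any mannitol array (range 0.00427 to 0.235).

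In proliferating leaf, members of the stress transcription factor list (10 of 20) and of the alternative respiration list (8 of 23) rose with mannitol. These lists kept their call with an estimated correlation (adjusted p = 0.0012 and 0.00494). The largest rise was that of AT1G65500, from 4.15 ± 0.0825 to 8.95 ± 0.846 (SD, n = 3; log2 change 4.80 ± 0.279 SE, adjusted p = 2.4e-10). It was followed by AT2G43590 (4.46), the lectin-like AT3G16530 (4.14), AT2G43620 (4.08), the blue copper-binding protein BCB (AT5G20230, 3.56), the transcription factor WRKY30 (AT5G24110, 3.42), PNP-A (3.40) and the indole glucosinolate methyltransferase IGMT4 (AT1G21130, 3.27), with adjusted p from 5.34e-10 to 0.000673. The alternative oxidase AOX1A, which accepts electrons upstream of the cytochrome pathway, rose from 5.45 ± 0.518 to 8.02 ± 0.895 (SD, n = 3; 2.57 ± 0.286 SE, adjusted p = 4.22e-06). Of 23 genes of alternative respiration and mitochondrial stress 8 rose (8 adjusted over the list alone; median 0.12, camera adjusted p = 3.22e-06, and adjusted p = 0.00494 with an estimated correlation), among them UPOX (AT2G21640, 2.11), BCS1 (AT3G50930, 0.78) and NDB2 (0.87). Stress ERF, WRKY and ZAT factors rose for 10 of 20 genes (13 adjusted over the list alone; median 0.69, adjusted p = 4.68e-19, and adjusted p = 0.0012 with an estimated correlation), with ERF5 (1.40), WRKY33 (1.08) and MYB51 (AT1G18570, 0.99) among them. The count of 8 was 5 without control replicate 3 or mannitol replicate 1, and the count of 10 was 6 without control replicate 3 and 5 without mannitol replicate 1.

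Other proliferating leaf lists had camera calls that did not hold with an estimated correlation. Of 19 salicylate genes 3 rose, including CYP71A13 (2.42) and PR5 (2.19), 4 adjusted over the list alone (median 0.04, adjusted p = 0.00661, and adjusted p = 0.427 with an estimated correlation). The mitochondrial genome had 2 rises of 31, and 4 adjusted over the list alone (median 0.09, adjusted p = 0.009, and adjusted p = 0.323 with an estimated correlation). The plastid genome had 1 of 73, and 2 adjusted over the list alone (median 0.11, adjusted p = 1.11e-05, and adjusted p = 0.427 with an estimated correlation). The median was lower for flavonoids (-0.22; 0 of 14, 1 adjusted over the list alone; adjusted p = 0.0314, and adjusted p = 0.472 with an estimated correlation). It was lower for stomatal lineage markers too (-0.19; 0 of 13, 2 adjusted over the list alone; adjusted p = 0.0214, and adjusted p = 0.323 with an estimated correlation). Meristem markers were lower (-0.12; 0 of 13, 0 adjusted over the list alone; adjusted p = 0.0311, and adjusted p = 0.427 with an estimated correlation), as were aquaporins (-0.07; 1 of 14 fell, 2 adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.323 with an estimated correlation). With the replicate block 4 further lists passed: abscisic acid (adjusted p = 0.0525, blocked 0.0499; RD22, 0.71, and the phosphatase ABI1, AT4G26080, 0.66, rose), senescence (0.0598, blocked 0.0415), expansins and XTH (0.0711, blocked 0.0499) and trichome markers (0.0598, blocked 0.0415). The senescence list had a median of -0.03 but a mean of 0.34 and an upward test, since 3 of 16 members rose (3 adjusted over the list alone), led by SAG21 (AT4G02380, 3.05) and WRKY53 (AT4G23810, 1.34). With the block, 7 plastid genome transcripts rose, and 1 gene fell in each of the stomatal lineage, meristem, abscisic acid and trichome lists. Single arrays moved small counts. The mitochondrial count of 2 was 1 without control replicate 1 or mannitol replicate 2, and 0 without mannitol replicate 1. The plastid count of 1 was 0 without control replicate 1, 3 without control replicate 2 and 2 without mannitol replicate 1. The aquaporin count of 1 was 0 without control replicate 1 or 2 or mannitol replicate 2 or 3. Without mannitol replicate 2 there were 2 falls in the stomatal lineage and 1 in abscisic acid, and without control replicate 2 there was 1 in the meristem list.

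Falls in proliferating leaf were few: the carnitine transporter OCT3 (AT1G16390, -1.18, adjusted p = 0.000122), XTH6 (-1.09), AT5G62210 (-1.02), AT4G30650 (-0.86), AT2G22510 (-0.82), the arabinogalactan protein AGP21 (AT1G55330, -0.75), AT2G45840 (-0.73) and AT2G44850 (-0.73). OCT3 and AT2G45840 kept the call in all 13 alternatives. Each of the others lost it in at least 1, with the highest adjusted p at 0.0703 for XTH6 and 0.0881 for AGP21 (both in the fit of the stage alone), and 0.217, 0.334, 0.248 and 0.148 for AT5G62210, AT4G30650, AT2G22510 and AT2G44850. These 4 all failed without control replicate 2 or without mannitol replicate 1, and all but AT2G44850 in the fit of the stage alone; AT2G22510 and AT2G44850 failed also without control replicate 1, and AT4G30650 without control replicate 3 or mannitol replicate 3. Panel genes that did not pass were RD29A (-0.59), RAB18 (-0.06), ERF6 (0.66), GA2OX6 (0.35), CYCB1;1 (0.03), EXPA10 (0.31), TT4 (-0.36), PDF1.2 (0.17) and PR1 (-0.29), with adjusted p from 0.132 to 0.98; with the replicate block ERF6 (0.0276) and GA2OX6 (0.0463) passed. In total 377 genes were called, 327 higher and 50 lower, 371 of them without overlap (10% by chance), and 144 rises and 5 falls were of 2-fold or more. With the block 668 were called (503 and 165), with the fit of the stage alone 221, and without mannitol replicate 1 there were 238; NDB2 also lost its call without that array (adjusted p = 0.0835, range over 13 alternatives 0.00263 to 0.0835).

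In expanding leaf, more genes were called than at any other stage. At an unadjusted p under 0.05 the same contrasts gave more genes in mature leaf (4003) than in expanding leaf (3896). The lipid transfer gene LTP2 rose most in expanding leaf. It rose from 4.78 ± 0.371 to 10.9 ± 0.153 (SD, n = 3; log2 change 6.09 ± 0.268 SE, adjusted p = 9.09e-13). It was followed by AT2G43620 (5.61), ATPMEPCRB (4.94), AT1G65500 (4.86), PNP-A (4.64), AT1G72060 (4.38), the berberine bridge enzyme-like AT1G26380 (4.36) and IGMT1 (AT1G21100, 3.86), with adjusted p from 3.59e-13 to 5.17e-06. The largest fall was that of PCC1 (AT3G22231), a pathogen- and clock-controlled gene, from 11.1 ± 0.492 to 7.22 ± 0.215 (SD, n = 3; -3.92 ± 0.475 SE, adjusted p = 6.22e-06). AT1G19960 (-3.28), AT2G32160 (-2.25), AT5G03350 (-1.63), XTH24 (AT4G30270, -1.57), AT1G76240 (-1.46), BT5 (AT4G37610, -1.46) and AT1G71140 (-1.42) fell too, with adjusted p up to 0.0076. All 16 kept their calls in each of 13 alternatives.

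Among the expanding leaf lists, stress ERF, WRKY and ZAT factors rose for 9 of 20 genes (13 adjusted over the list alone; median 0.50, camera adjusted p = 2.84e-12, and adjusted p = 0.0127 with an estimated correlation), with WRKY33 (2.75), MYB51 (1.68), the zinc finger factor STZ (AT1G27730, 1.67) and ERF5 (1.06). Senescence genes rose for 4 of 16 (5 adjusted over the list alone; median 0.26, adjusted p = 0.000116, and adjusted p = 0.02 with an estimated correlation), with SAG21 (3.22), WRKY53 (1.52) and WRKY6 (AT1G62300, 1.45). Abscisic acid and dehydration genes rose for 11 of 27 (15 adjusted over the list alone; median 0.53, adjusted p = 1.88e-13), with the lipid transfer gene LTP3 (AT5G59320, 3.61), HB-7 (1.43), RD22 (1.38) and the dehydrin ERD10 (AT1G20450, 1.25). That list had adjusted p = 0.0852 with an estimated correlation, and the lists that follow also lost their calls with it. Mitotic genes rose for 4 of 20 (6 adjusted over the list alone; median 0.26, adjusted p = 0.000165, and adjusted p = 0.453 with an estimated correlation). Of these the kinase CDKB2;1 (AT1G76540, 0.55) kept its call in each of 13 alternatives, while the microtubule protein PLE (AT5G51600, 0.68, adjusted p = 0.0332) had 0.0511 with the replicate block (range over 13 alternatives 0.0168 to 0.187; 0.0769 to 0.187 without control replicate 2, mannitol replicate 2 or mannitol replicate 3; lost also in the fit of the stage alone, with quantile normalization and with array weights). The kinase AUR2 (AT2G25880, 0.58, 0.0477) failed without control replicate 1 or 2 or mannitol replicate 1 or 2, in the fit of the stage alone and with array weights (0.126 to 0.275, range 0.0101 to 0.275), and KN (0.48, 0.0478) without any 1 of the 6 arrays and with array weights (0.0694 to 0.125, range 0.0241 to 0.125). The count of 4 mitotic genes was thus 2 without control replicate 1, mannitol replicate 1 or mannitol replicate 3, and 1 without control replicate 2 or mannitol replicate 2. DNA replication genes had 1 rise of 16, and 1 adjusted over the list alone (adjusted p = 0.288), with a median of 0.01 that turned negative under centring; the count was 2 without control replicate 1 and 0 without control replicate 2 or mannitol replicate 2. Scavengers of reactive oxygen rose for 4 of 15 (4 adjusted over the list alone; median 0.21, adjusted p = 0.00186, and adjusted p = 0.104 with an estimated correlation), among them catalase CAT3 (AT1G20620, 0.81) and superoxide dismutase CSD1 (AT1G08830, 0.75). Of 14 glucosinolate genes 4 rose (4 adjusted over the list alone; median 0.02, mean 0.33, adjusted p = 0.0157, and adjusted p = 0.616 with an estimated correlation): CYP79B2 (2.14), CYP79B3 (AT2G22330, 1.28), CYP83B1 (0.89) and the sulfotransferase SOT16 (AT1G74100, 0.81). Guard cell markers fell for 2 of 6, KAT1 (-1.003) and MYB60 (-0.53) (2 adjusted over the list alone; median -0.29, adjusted p = 0.0125, and adjusted p = 0.168 with an estimated correlation); MYB60 lost its call without control replicate 1 or 3 or mannitol replicate 1 or 3 and in the fit of the stage alone (adjusted p 0.102 to 0.19, range over 13 alternatives 0.0124 to 0.19). Salicylate genes went both ways, with 5 rises such as PR5 (3.65) and 3 falls such as WRKY54 (AT2G40750, -1.11), 6 and 4 adjusted over the list alone, and the list passed the test with the replicate block (adjusted p = 0.0984, blocked 0.0202). Further counts moved by over 1.5 times with single arrays. The 9 stress factors were 5 without mannitol replicate 1, and the 11 abscisic acid genes 7 without control replicate 1. The 4 scavengers were 2 without control replicate 2 or mannitol replicate 3. The 5 salicylate rises were 3 without control replicate 2 or mannitol replicate 1 or 3. The 2 guard cell falls were 1 without control replicate 1 or 3 or mannitol replicate 1 or 3. With the block 1 glucosinolate gene fell.

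In the panel, RD29A (1.52, adjusted p = 0.00161), ERF5 (1.06, 0.000204) and the expansin EXPA10 (0.56, 0.00973) rose in expanding leaf. EXPA10 lost its call without control replicate 2 (0.0667) or mannitol replicate 3 (0.0528) and in the fit of the stage alone, with a range over 13 alternatives of 0.00347 to 0.1. Those that did not pass were AOX1A (-0.01), NDB2 (0.51), RAB18 (0.43), ERF6 (0.67), GA2OX6 (0.13), CYCB1;1 (0.41), TT4 (-0.02), PDF1.2 (1.12) and PR1 (-0.08), with adjusted p from 0.0928 to 0.993; with the block NDB2 (0.0369), ERF6 (0.0102), CYCB1;1 (0.0435) and PDF1.2 (0.0376) passed. In total 1589 genes were called, 836 higher and 753 lower, 1519 of them without overlap (10% by chance). At a change of 2-fold or more there were 258 rises and 41 falls. The fit of the stage alone called 832 (524 and 308). With the replicate block 2184 were called, and falls outnumbered rises (1069 higher and 1115 lower). They also did after centring (784 and 829), with dim genes left out (776 and 799) and without control replicate 2 (825 and 886).

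In mature leaf, 9 of 31 transcripts of the mitochondrial genome fell with mannitol (5 without mannitol replicate 2), and the list kept its call with an estimated correlation (adjusted p = 0.00665). Abscisic acid and glucosinolate genes rose for 9 of 27 and 5 of 14, and these lists lost their call (adjusted p = 0.169 each with an estimated correlation). The glucosinolate count was 0 without control replicate 3 or mannitol replicate 2, 1 without mannitol replicate 1 and 3 without mannitol replicate 3. LTP3 rose most, from 4.74 ± 0.866 to 10.97 ± 0.257 (SD, n = 3; log2 change 6.23 ± 0.508 SE, adjusted p = 9e-08). The late embryogenesis abundant proteins LEA7 (AT1G52690, 3.70) and LEA4-5 (AT5G06760, 2.13), AT3G02480 (2.59), AT1G27030 (2.103), the beta-glucosidase PYK10 (AT3G09260, 2.09), AT1G75900 (2.02) and AT3G13672 (1.86) also rose, with adjusted p from 5.7e-09 to 0.00281. PYK10 is a member of the root marker list, of which it was the only riser among 10 genes (1 adjusted over the list alone; median -0.12 but mean 0.11, camera adjusted p = 0.95). The falls included BT5 (-1.67), the raffinose synthase family gene DIN10 (AT5G20250, -1.65), XTH24 (-1.50), AT1G71140 (-1.40), the senescence factor NAC6 (AT5G39610, -1.38), the auxin-related glucosyltransferase UGT74E2 (AT1G05680, -1.28), RAV1 (AT1G13260, -1.24) and AT2G32160 (-1.24), with adjusted p up to 0.0456.

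Transcripts of the mitochondrial genome fell for 9 of 31 loci in mature leaf (16 adjusted over the list alone; median -0.42, camera adjusted p = 5.44e-11, and adjusted p = 0.00665 with an estimated correlation), among them ATMG00640 (-0.95), ATMG00690 (-0.83) and ATMG00160 (-0.79). Plastid genome transcripts had 0 of 73 calls, also 0 adjusted over the list alone, and a median of 0.05 (adjusted p = 0.0622). Abscisic acid and dehydration genes rose for 9 of 27 (11 adjusted over the list alone; median 0.39, adjusted p = 5.44e-11, and adjusted p = 0.169 with an estimated correlation), with RD29B (AT5G52300, 1.61), LTP4 (AT5G59310, 1.61) and RD22 (1.09). Glucosinolate synthesis rose for 5 of 14 genes (12 adjusted over the list alone; median 0.59, adjusted p = 6.41e-10, and adjusted p = 0.169 with an estimated correlation), among them the regulator MYB29 (AT5G07690, 0.97) and CYP79B2 (0.91). Heat shock genes fell for 3 of 13 (7 adjusted over the list alone; median -0.36, adjusted p = 8.76e-05, and adjusted p = 0.27 with an estimated correlation): the heat stress factor HSFA2 (AT2G26150, -1.78), HSP101 (AT1G74310, -1.28) and DREB2A (AT5G05410, -0.65). Control and mannitol values of HSFA2 overlapped, since its control arrays ranged from 3.78 to 6.65. Those of HSP101 overlapped too (control replicate 2 at 5.81, mannitol replicate 1 at 5.95), while those of DREB2A did not. Vascular markers had a median of 0.26 with 0 of 10 calls, also 0 adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.516 with an estimated correlation). The stress ERF, WRKY and ZAT list had 0 of 20 calls, 0 adjusted over the list alone, and a median of -0.06 against a test direction of up (adjusted p = 0.985). Senescence genes had 3 falls of 16 and no rise (5 falls and 2 rises adjusted over the list alone; adjusted p = 0.667), with a median of 0.04, which changed sign between scalings, and a mean of -0.10. Single arrays moved these counts. The 9 mitochondrial falls were 5 without mannitol replicate 2, and the 5 glucosinolate rises 0 without control replicate 3 or mannitol replicate 2, 1 without mannitol replicate 1 and 3 without mannitol replicate 3. The 3 heat shock falls were 1 without control replicate 1 or mannitol replicate 2 and 7 without control replicate 2. The 3 senescence falls were 1 without mannitol replicate 2, and without control replicate 2 there was 1 senescence rise. There was 1 vascular rise without control replicate 1 or 2, 1 stress factor rose without mannitol replicate 1, and 2 plastid transcripts rose and 1 fell without control replicate 2. With the replicate block, whose pairing check did not pass at this stage, 13 mitochondrial transcripts and 7 heat shock genes fell. In that fit 11 abscisic acid and 12 glucosinolate genes rose.

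In the mature panel, RD29A (1.40, adjusted p = 0.00666) and TT4 (1.16, 0.00161) rose. The remaining values were AOX1A -0.33, NDB2 -0.25, RAB18 0.49, ERF5 0.06, ERF6 -0.20, GA2OX6 -0.17, CYCB1;1 -0.22, EXPA10 0.29, PDF1.2 1.095 and PR1 0.90, with adjusted p from 0.238 to 0.897. In total 1003 genes were called, 621 higher (61.9%) and 382 lower, 959 of them without overlap (10% by chance), and 71 rises and 26 falls were of 2-fold or more; after centring each array on its median 480 were higher (43.4%) and 627 lower. The fit of the stage alone called 481. The count moved with single arrays: 560 without control replicate 1, 1564 without control replicate 2, 476 without control replicate 3, 507 without mannitol replicate 2 and 535 without mannitol replicate 3. The same holds for some named genes. RD29A lost its call without control replicate 1 (0.0578, range over 13 alternatives 0.000361 to 0.0578). UGT74E2 lost it without control replicate 1 or 3 or mannitol replicate 2 or 3 and in the fit of the stage alone (0.0564 to 0.207, range 0.00975 to 0.207). MYB29 lost it without control replicate 1 or 3 or mannitol replicate 2 and in the fit of the stage alone (0.0525 to 0.111, range 0.000193 to 0.111), and CYP79B2 without control replicate 3 or mannitol replicate 1 or 2 (0.0658 to 0.142, range 0.00125 to 0.142). For HSP101 this was without control replicate 1 or mannitol replicate 2 and in the fit of the stage alone (0.0548 to 0.121, range 8.93e-05 to 0.121), for DREB2A without any array but control replicate 2 and in the fit of the stage alone (0.0507 to 0.16, range 0.00472 to 0.16), and for HSFA2 in the fit of the stage alone (0.147, range 8.4e-08 to 0.147).

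**Figure D1:**
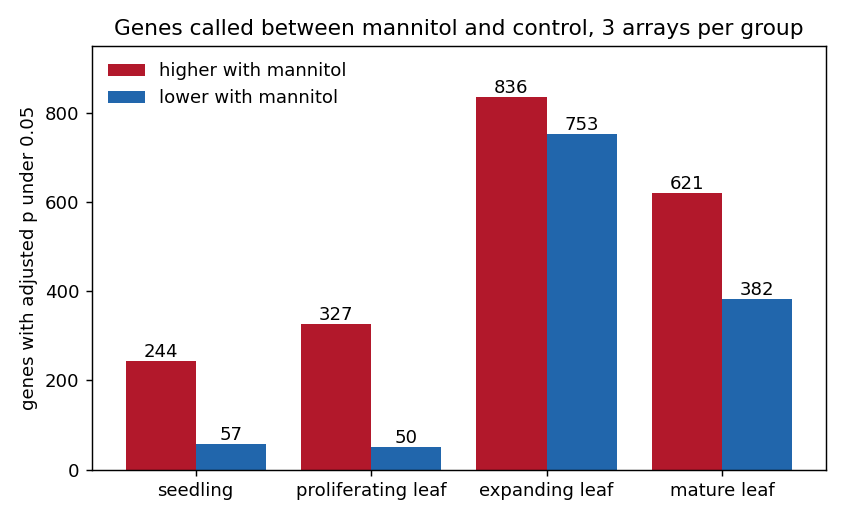
Number of genes that rose or fell with mannitol at each stage (adjusted p under 0.05, limma, 3 control and 3 mannitol arrays per stage). Rises outnumber falls in seedlings (244 against 57) and proliferating leaf (327 against 50). In expanding leaf (836 against 753) the order turns with the replicate block (1069 against 1115) and after median centring (784 against 829), and in mature leaf (621 against 382) it turns after median centring (480 against 627).

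**Figure D2:**
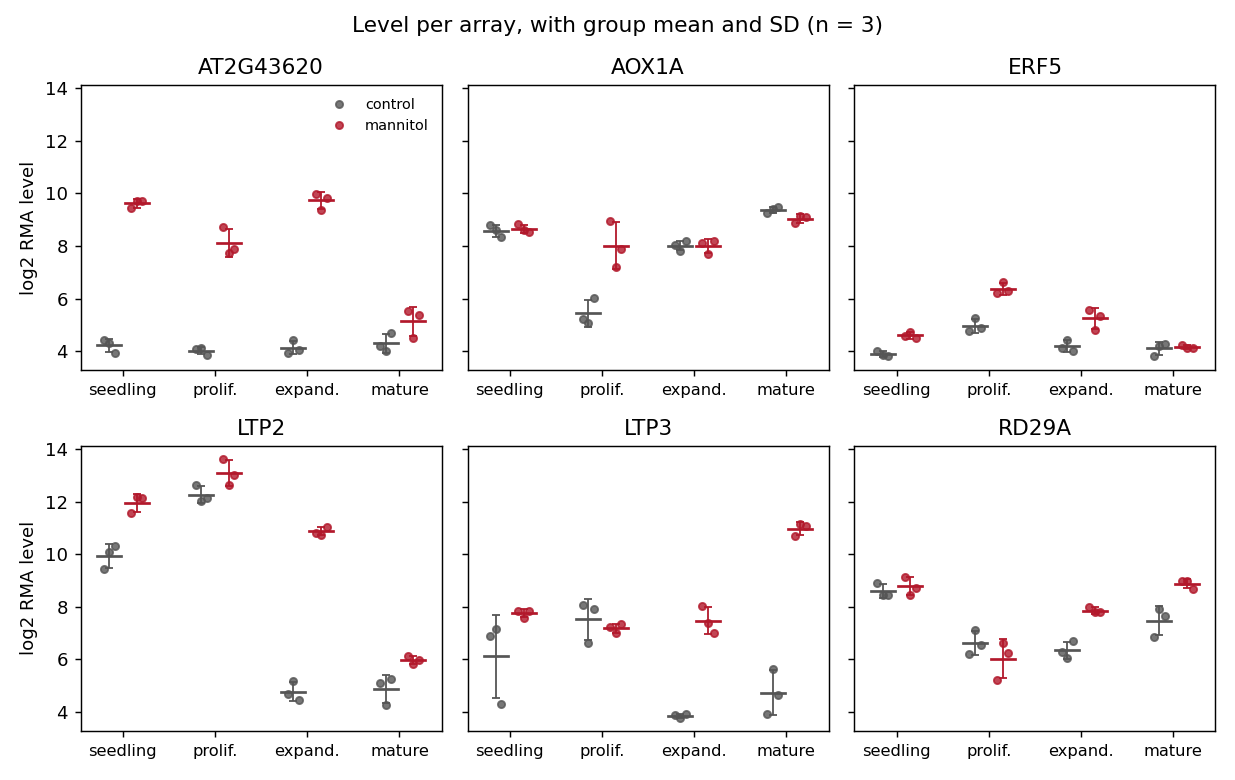
Log2 RMA level of 6 genes in each array by stage, control and mannitol, with the group mean and SD (n = 3). AT2G43620 rose by 5.40 in seedlings and 5.61 in expanding leaf, AOX1A rose by 2.57 in proliferating leaf, and LTP3 rose by 6.23 in mature leaf.

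The test of the difference between stages showed that many of these effects differed between the leaf stages. Each leaf stage was harvested on its own day. Leaf stage therefore cannot be told apart from plant age, harvest or the time of growth on mannitol. Over the 3 leaf stages, 979 genes had unequal effects by the F test, among them 234 of the 377 genes called in proliferating leaf, 569 of the 1589 in expanding leaf and 398 of the 1003 in mature leaf. The block gave 1768, though in mature leaf the replicate numbers did not pass as pairs. LTP2 had the smallest p (F = 122, adjusted p = 1.83e-08): its change was 0.83 in proliferating, 6.09 in expanding and 1.12 in mature leaf, from control levels of 12.3, 4.78 and 4.88. ATPMEPCRB (F = 118; 2.07, 4.94 and 0.65), AT2G43620 (F = 92.8; 4.08, 5.61 and 0.85) and AT1G02360 (F = 84.2; 1.66, 2.88 and 0.21) were also highest in expanding leaf. The glycine-rich protein GRP-3 (AT2G05520, F = 100.3; 2.91, 1.34 and 0.44), the sugar transporter STP4 (AT3G19930, F = 85.1; 2.48, 1.45 and -0.45) and AT3G10930 (F = 74.0; 2.28, 0.41 and 0.19) were highest in proliferating leaf. AT1G19960 (F = 86.7) had changes of -0.04, -3.28 and -0.11. Adjusted p for these 8 genes was at most 4.37e-07. Of the panel, AOX1A (F = 30.98, adjusted p = 0.000125), ERF5 (F = 16.8, 0.00335), RD29A (F = 15.9, 0.00438), TT4 (F = 14.7, 0.00629) and NDB2 (F = 10.1, 0.0252) differed between leaf stages. The control arrays of AOX1A lay at 5.1 to 6.0 in proliferating leaf, 7.8 to 8.2 in expanding leaf and 9.2 to 9.5 in mature leaf.

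Between proliferating and expanding leaf the abscisic acid list shifted up by a median of 0.44 (camera adjusted p = 1.47e-07, and adjusted p = 0.366 with an estimated correlation) and the mitotic list by 0.37 (adjusted p = 0.00018, and adjusted p = 0.611 with an estimated correlation). Between expanding and mature leaf the stress ERF, WRKY and ZAT list shifted by -0.61 (adjusted p = 7.78e-09, and 0.0235 with an estimated correlation) and the senescence list by -0.34 (adjusted p = 6.62e-05, and 0.0235 with an estimated correlation). Between proliferating and mature leaf the stress factor list shifted by -0.78 (adjusted p = 1.92e-09, and 0.0205 with an estimated correlation), the mitochondrial genome by -0.41 (adjusted p = 1.59e-12, and 0.00341 with an estimated correlation) and alternative respiration by -0.14 (adjusted p = 0.000449, and 0.0316 with an estimated correlation). With the replicate block, 3 further lists passed between proliferating and expanding leaf: senescence (0.0388), DNA replication (0.0411) and stomatal lineage (0.0415). Single genes whose effect differed numbered 270 between proliferating and expanding leaf (134 higher and 136 lower in expanding leaf; 534 with the replicate block, 262 and 272; 145 in the fit of these stages alone), 709 between expanding and mature leaf (344 and 365; 434 in the fit of these stages alone) and 548 between proliferating and mature leaf (261 and 287). In the same order, differences of 2-fold or more numbered 70 higher and 42 lower, 77 and 187, and 85 and 149. The block gave 1339 between expanding and mature and 1014 between proliferating and mature leaf. Of the counts over all sizes, the first was 175 without proliferating control replicate 3; the second was 1070 without expanding control replicate 2 and 436 without mature mannitol replicate 2; the third was 359 without proliferating mannitol replicate 1 and 337 without mature mannitol replicate 2.

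**Figure D3:**
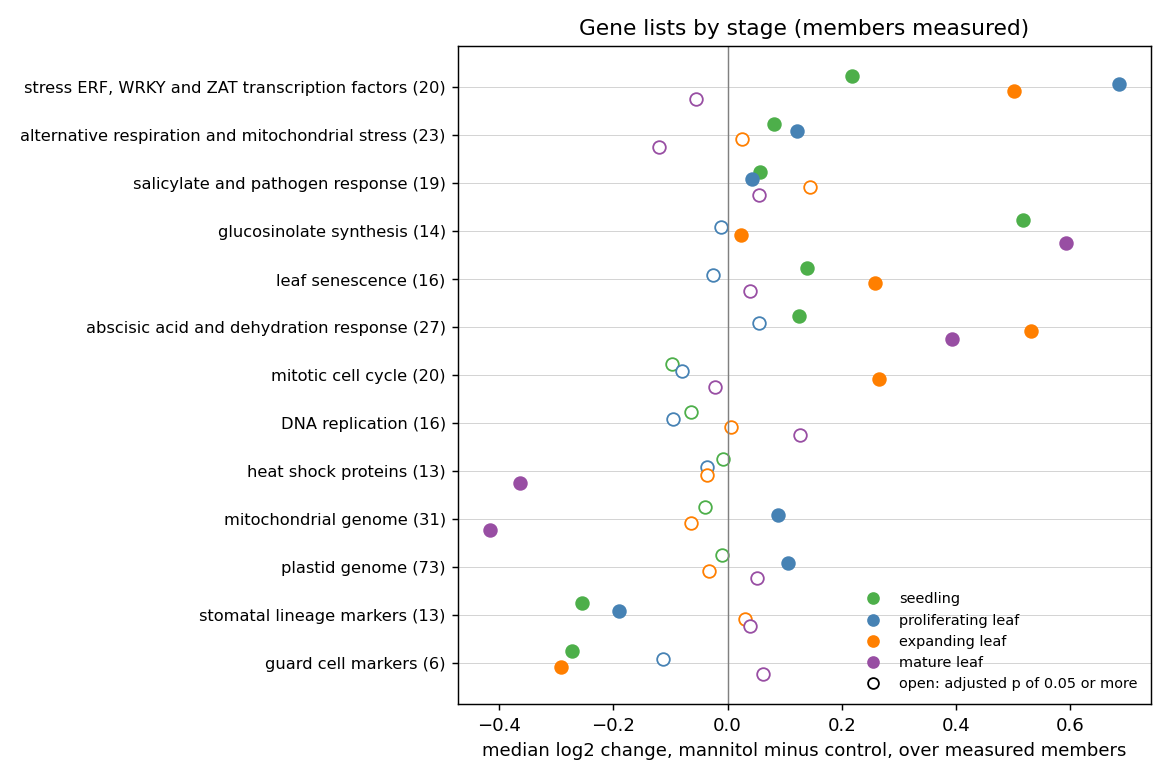
Median log2 change with mannitol over the measured members of 13 gene lists at each stage; filled points passed the camera test and open points did not. Stress transcription factors lie at 0.69 in proliferating and 0.50 in expanding leaf against -0.06 in mature leaf, and the mitochondrial genome lies at -0.42 in mature leaf; the open points of glucosinolates in proliferating leaf, DNA replication in expanding leaf and mitotic, senescence and stomatal lineage genes in mature leaf change sign between scalings.

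The stages shared many rises. Seedlings and expanding leaf had 201 rises in common (82.4% of the 244 in seedlings) where independent lists would share 9.82. Proliferating and expanding leaf shared 209 (13.2) and seedlings and proliferating leaf 113 (3.84). With mature leaf, expanding leaf shared 146 (25.0), seedlings 52 (7.29) and proliferating leaf 22 (9.77; Fisher's exact adjusted p = 0.000399). Shared falls were 92 between expanding and mature leaf (13.8 for independent lists), 33 between seedlings and expanding leaf (2.07) and 15 between proliferating and expanding leaf (1.81). There were 13 between seedlings and mature leaf (1.05), 5 between seedlings and proliferating leaf (0.137) and 3 between proliferating and mature leaf (0.919; Fisher's exact adjusted p = 0.0641). In all 4 stages 16 genes rose, including the chitinase CHI (AT2G43570; 2.47, 2.33, 3.84 and 1.73 from seedling to mature leaf), RD22 (0.87, 0.71, 1.38 and 1.09), the monolignol glucosyltransferase UGT72E1 (AT3G50740; 1.39, 0.91, 2.38 and 1.35) and CYP79B2 (1.49, 1.61, 2.14 and 0.91). XTH6 fell in all 4 (-1.05, -1.09, -1.37 and -0.92). In mature leaf its call was lost without control replicate 1 (0.0602) or 3 (0.0533), with a range over 13 alternatives of 0.00174 to 0.0602. That of CYP79B2 in mature leaf was lost without control replicate 3 or mannitol replicate 1 or 2 (0.0658 to 0.142, range 0.00125 to 0.142). Another 92 genes rose in seedlings, proliferating and expanding leaf without being called higher in mature leaf. Genes called in opposite directions numbered 22 between expanding and mature leaf, 13 between proliferating and mature leaf and at most 3 between other pairs. Across all genes, which are not independent replicates, the log2 changes correlated with r = 0.67 between seedlings and expanding leaf, 0.55 between seedlings and proliferating leaf and 0.52 between proliferating and expanding leaf, against 0.26 (expanding), 0.21 (seedlings) and 0.11 (proliferating) with mature leaf. Rank correlations were 0.34, 0.20 and 0.17 against 0.15, 0.11 and 0.13, in the same order. No stages share arrays.

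**Figure D4:**
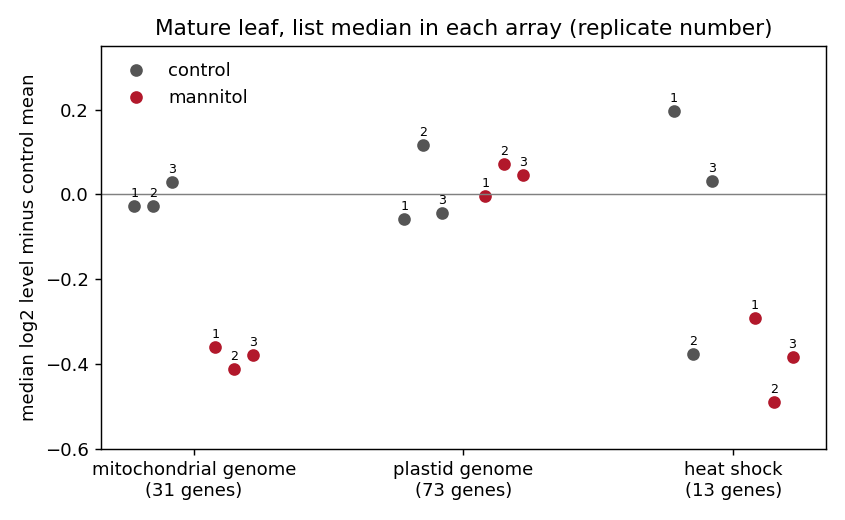
Median log2 level of 3 gene lists in each mature leaf array, relative to the mean of the control arrays, with the replicate number at each point. The mitochondrial genome lies at -0.36, -0.41 and -0.38 with mannitol and between -0.03 and 0.03 in the control arrays, the plastid genome overlaps between groups, and the heat shock list spreads from -0.38 to 0.20 in the control arrays.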

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

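The comparison of the mitochondrial with the plastid genome and its scaling, the spread of heat shock genes in control arrays, the comparison of mitotic with DNA replication genes, and the exchange of labels in expanding leaf were chosen after the result was seen. What marks the results of this part is a mannitol effect that differs between leaf stages.

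Over the 3 leaf stages 979 genes had unequal effects. Of the 41 genes named for a leaf stage, chosen for the size of their effect, 33 were among them, against 891 of the 2470 genes called at any leaf stage (36.1%). Between pairs of stages the effect differed for 270 genes (proliferating and expanding), 709 (expanding and mature) and 548 (proliferating and mature). Of 100 relabelings of arrays within stages, the real labelling included, 1 gave as many calls in the F test (next highest 714), 4 between proliferating and expanding leaf (818), 1 between expanding and mature leaf (500) and 1 between proliferating and mature leaf (279). These shares are under 0.05. Mixing the labels within a stage also breaks up a mannitol effect that the stages share and adds it to the spread. The shares therefore cannot tell unequal effects from a shared effect. The relabeling behind 714, 500 and 279 exchanged the labels of expanding and mature leaf as a whole, so it still holds their treatment effects. In the 3 other relabelings with 270 or more calls (362, 401 and 818), the arrays of expanding leaf kept their real grouping, either as labelled or with the labels exchanged as a whole. Their counts therefore hold the treatment effect of expanding leaf. Exchanging the labels of expanding leaf alone, which adds the effects of the 2 stages, gave 1413.

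By gene, F was 122 for LTP2, 118 for ATPMEPCRB, 100.3 for GRP-3 and 92.8 for AT2G43620. It was 86.7 for AT1G19960, 85.1 for STP4, 84.2 for AT1G02360 and 74.0 for AT3G10930. In the panel it was 30.98 for AOX1A, 10.1 for NDB2, 15.9 for RD29A, 16.8 for ERF5 and 14.7 for TT4.

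From proliferating to expanding leaf the list effect shifted by 0.44 for abscisic acid (adjusted p = 1.47e-07, and adjusted p = 0.366 with an estimated correlation), by 0.37 for mitotic genes (adjusted p = 0.00018, and adjusted p = 0.611 with an estimated correlation) and by 0.16 for reactive oxygen scavenging (adjusted p = 0.0079, and adjusted p = 0.366 with an estimated correlation). It shifted by -0.11 for the mitochondrial genome (adjusted p = 0.00858, and adjusted p = 0.366 with an estimated correlation) and by -0.13 for the plastid genome (adjusted p = 0.000447, and adjusted p = 0.681 with an estimated correlation).

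From expanding to mature leaf the effect on stress ERF, WRKY and ZAT factors shifted by -0.61 and that on senescence genes by -0.34, the shifts that kept their call with an estimated correlation. The mitochondrial genome shifted by -0.26 (adjusted p = 6.43e-05, and adjusted p = 0.0705 with an estimated correlation) and mitotic genes by -0.28 (adjusted p = 0.00262, and adjusted p = 0.439 with an estimated correlation). Alternative respiration shifted by -0.13, ethylene by -0.15, reactive oxygen scavenging by -0.12 and heat shock by -0.25. Upward shifts were 0.16 for expansins and XTH, 0.16 for aquaporins, 0.32 for guard cell markers, 0.39 for vascular markers and 0.088 for the plastid genome. For these 9 lists the adjusted p was 0.00504 to 0.0354, and adjusted p = 0.214 to 0.855 with an estimated correlation.

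From proliferating to mature leaf the effect shifted by -0.78 for stress factors, -0.41 for the mitochondrial genome and -0.14 for alternative respiration, and these kept their call with an estimated correlation. Downward shifts without it were -0.16 for ethylene, -0.23 for senescence and -0.38 for heat shock. Upward shifts were 0.38 for abscisic acid, 0.15 for DNA replication, 0.14 for expansins and XTH, 0.21 for flavonoids, 0.53 for glucosinolates, 0.12 for aquaporins and 0.39 for vascular markers. For these 10 lists the adjusted p was 0.000136 to 0.0206, and adjusted p = 0.136 to 0.482 with an estimated correlation.

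Lower transcripts of the mitochondrial genome in mature leaf are not matched by the plastid genome, whose median change was 0.051 (95% bootstrap interval over genes 0.014 to 0.087). That interval does not measure the spread between arrays, and the plastid medians of the control arrays ran from -0.059 to 0.116. A loss of organelle RNA in general would lower the transcripts of both genomes. The mitochondrial median stayed at -0.37 or lower under quantile normalization and centring, and between -0.42 and -0.37 with any single array left out (highest camera p 3.61e-09). The 3 mannitol arrays lay at -0.36, -0.41 and -0.38, and the 3 control arrays between -0.03 and 0.03. Fewer mitochondrial genomes or a lower rate of their transcription could give these values, but neither was measured and other causes remain possible. The same list rose from expanding to mature control leaf, a step that shares the 3 mature control arrays. Whether the lower values with mannitol belong to that step was not tested.

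Lower heat shock transcripts in mature leaf go with a wide spread among the control samples. The 3 control arrays spread over 0.57 in the list median, against a group difference of -0.34 and a spread of 0.20 in the mannitol arrays. HSFA2 had 6.65, 3.78 and 5.56 in the control arrays and 3.87, 3.42 and 3.38 in the mannitol arrays. With any single array left out the highest camera p was 0.00116; the list had adjusted p = 0.27 with an estimated correlation. A heat response in control replicates 1 and 3 may account for the difference, which was not tested. For DREB2A, control replicate 2 (5.45) also lay above the mannitol arrays (5.07 to 5.32).

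In expanding leaf the median effect on mitotic genes exceeded that on DNA replication genes by 0.26 (95% bootstrap interval over genes 0.040 to 0.42, which does not measure the spread between arrays). Both lists fell from proliferating to mature control leaf (-4.08 and -4.06), and a leaf held back in development was taken to raise both. That is an assumption and was not tested. The lists fell by different amounts within each step between these stages, so a held back leaf need not raise them equally. Per array the difference was -0.11, 0.19 and -0.08 in control and 0.17, 0.37 and 0.19 with mannitol. The groups overlap, but within the pairs of replicate numbers the difference was higher with mannitol each time, by 0.28, 0.19 and 0.27. The median effect on mitotic genes was 0.249 or more under other scalings, and the highest camera p with any single array left out was 0.000607; the list had adjusted p = 0.453 with an estimated correlation. With 3 pairs and groups that overlap, whether the leaf as a whole was younger stays open.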

How the results depend on the processing

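No call turned its direction: 0 of 667 named gene results under any alternative, 0 of 297 list results with an estimated correlation or fry, and 0 of 231 with the block. For lists a turn was counted only where both tests made a call. Without that, the direction differed for 16 list results with fry and 11 with the block. Some alternatives could not turn a direction. An estimated correlation keeps that of camera, and the fit of the compared stages alone, the block, the trend and the dim filter keep the log2 change of a gene. List medians near 0 did change sign between scalings, for lists without a call: proline, glucosinolates and clock in proliferating leaf, DNA replication in expanding leaf, and gibberellin, mitotic, photosynthesis, jasmonate, senescence, iron and stomatal lineage in mature leaf. Of 258 gene calls, 172 held under every alternative and 86 were lost in at least 1; the cause was not tested. With few arrays and a fit of the compared stages alone, fewer degrees of freedom are left, and 59 calls were lost there, against 4 with the replicate block, 2 with an intensity trend, 11 with quantile normalization, 7 with centring and 9 with array weights. Of 297 list results, 67 lost their call with an estimated correlation and 31 with fry. The block ended the call of aquaporins between proliferating and mature leaf (adjusted p = 0.0206, blocked 0.0505). In mature leaf the replicate numbers did not pass the pairing check (0.29, 0.42 and 0.059, limit 0.1). Even so, each of the 6 arrays there correlated best with the array of its own number in the other group. With the block DNA replication (0.0367), meristem markers (0.0377) and the plastid genome (0.015) would be called there. Low signal may limit the calls in dim genes, which was not tested. By their highest group mean, 6706 genes lay below the level of 5.11.

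Counts of called genes were as follows. With own stages only: 221 in proliferating, 832 in expanding and 481 in mature leaf, 145 for proliferating against expanding and 434 for expanding against mature leaf. With the replicate block: 492 in seedlings, 668 in proliferating, 2184 in expanding and 1813 in mature leaf, 534, 1339 and 1014 for the stage pairs in the order of the report and 1768 for the F test. With array weights: 889 in seedlings, 1637 in mature leaf and 1085 for expanding against mature leaf. With a fold minimum of 2: 117, 149, 299 and 97 from seedlings to mature leaf, 112, 264 and 234 for the stage pairs, 395 for the F test, and 5054 and 1675 for development. With single arrays left out: 185 to 287 in seedlings, 238 to 457 in proliferating, 1121 to 1711 in expanding and 476 to 1564 in mature leaf, 175 to 301, 436 to 1070 and 337 to 750 for the stage pairs, and 679 to 1298 for the F test. Shared falls of proliferating and mature leaf were 3.26 times those of independent lists (adjusted p = 0.0641) and 1.81 times (0.00548) with genes at an unadjusted p under 0.01.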

Other observations

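The tests of the development axis in this part were chosen after the result was seen. Single gibberellin, wall and water channel genes changed with mannitol in expanding and mature leaf, where these lists were not called. In expanding leaf 2 of 29 gibberellin genes rose and 3 fell, 4 of 38 expansin and XTH genes rose and 6 fell, and 1 of 14 aquaporins rose and 3 fell. In mature leaf the rises and falls were 4 and 2, 5 and 3, and 2 and 0, in the same order. GASA1 fell in expanding (-1.02) and mature leaf (-0.90) as in seedlings, while its relative GASA4 (AT5G15230) rose in expanding (1.06) and mature leaf (1.74). The synthesis genes GA3 (AT5G25900; 0.66 and 0.69) and, in mature leaf, GA3OX1 (AT1G15550, 0.91) rose, and GA20OX1 (AT4G25420) fell in expanding leaf (-0.70). In expanding leaf the wall enzyme XTH19 (AT4G30290) rose (1.76) and XTH17 fell (-0.73). In mature leaf the expansins EXPB1 (AT2G20750, 1.43) and EXPA4 (AT2G39700) rose, the latter by 1.104. The aquaporin PIP1;5 (AT4G23400) fell (-1.12) and PIP2;5 (AT3G54820) rose (0.75) in expanding leaf, and PIP2;5 rose in mature leaf (0.47).

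In expanding leaf the auxin (2 of 13 rose and 3 fell, 2 and 5 adjusted over the list alone), cytokinin (0 and 1 of 10, 1 and 1 adjusted over the list alone) and jasmonate lists (2 and 1 of 16, 3 and 1 adjusted over the list alone) were not called (adjusted p = 0.277, 0.562 and 0.562), and members went both ways. The block gave 3 auxin rises and 5 falls, and 4 jasmonate rises. The 2 auxin rises were 1 without control replicate 1 or mannitol replicate 2 and 0 without control replicate 3 or mannitol replicate 1 or 3, and the 3 falls were 1 without control replicate 3 or mannitol replicate 3. The jasmonate fall was lost without any 1 of the 6 arrays, and 1 cytokinin gene rose without mannitol replicate 1. IAA6 (AT1G52830), an auxin response repressor, fell (-0.99), as did the cytokinin response regulator ARR15 (AT1G74890, -0.98), the cell cycle inhibitors SMR1 (AT3G10525, -0.64) and KRP1 (AT2G23430, -0.54), the trichome repressor TRY (AT5G53200, -0.81) and the clock-related RVE1 (AT5G17300, -0.68). GH3.5 (AT4G27260) rose by 0.72 (adjusted p = 0.0115) and JAZ9 (AT1G70700) fell by 0.69 (0.0378). GH3.5 lost its call without control replicate 3 or mannitol replicate 1 or 3 and in the fit of the stage alone (0.0586 to 0.101, range over 13 alternatives 0.000984 to 0.101), and JAZ9 with any single array left out (0.0611 to 0.129, range 0.00174 to 0.129). The jasmonate repressor JAZ1 (AT1G19180, 1.60), the jasmonate synthesis gene OPR3 (AT2G06050, 0.67) and the mitochondrial carriers UCP5 (AT2G22500, 2.27) and DIC2 (AT4G24570, 1.22) rose. UCP5 (1.09) and the flavonol synthase FLS1 (AT5G08640, 0.87) rose in mature leaf, where the proline dehydrogenase ERD5 (AT3G30775, -1.09) and TPS11 (AT2G18700, -0.81) fell. PYK10 rose in expanding (1.91) and mature leaf, and in control leaves fell by 4.55 from proliferating to expanding leaf.

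Lists without a call had these medians and adjusted p from seedlings to mature leaf. Gibberellin: 0.04 (0.989), -0.07 (0.599), 0.02 (0.989) and -0.01 (0.479). Raffinose and trehalose: -0.10 (0.989), -0.02 (0.424), -0.05 (0.581) and -0.14 (0.536). Proline: 0.07 (0.169, blocked 0.0412), 0.01 (0.451), -0.01 (0.834) and 0.09 (0.847). Endocycle: -0.05 (0.301), -0.24 (0.0675), -0.06 (0.462) and -0.07 (0.774). Growth regulators: 0.01 (0.989), -0.04 (0.831), 0.01 (0.581) and -0.15 (0.339). Photosynthesis: -0.03 (0.505), -0.02 (0.739), -0.01 (0.688) and 0.02 (0.264). Jasmonate: 0.09 (0.38), -0.03 (0.176), -0.05 (0.562) and 0.03 (0.774). Auxin: -0.06 (0.989), -0.12 (0.236), -0.22 (0.277) and -0.16 (0.339). Cytokinin: -0.01 (0.279), -0.11 (0.228), -0.13 (0.562) and -0.08 (0.852). Ethylene: -0.08 (0.485), -0.03 (0.0711), 0.12 (0.0984) and -0.08 (0.264). Iron: 0.35 (0.177, blocked 0.0198), 0.13 (0.311), -0.03 (0.787) and 0.04 (0.479). Circadian clock: 0.02 (0.579), 0.02 (0.632), -0.12 (0.288) and -0.14 (0.264). Median and mean differed in sign for gibberellin in seedlings, expanding and mature leaf and for cytokinin in seedlings. They also differed for ethylene, jasmonate and raffinose in proliferating leaf, jasmonate and iron in expanding leaf, and proline in mature leaf. In seedlings the test direction was up for raffinose and auxin, against the median.

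The mannitol effect and development were set against each other. Of 905 genes that fell at least 2-fold from expanding to mature control leaf, 185 rose with mannitol in mature leaf and 5 fell. Of 770 genes that rose at least 2-fold, 84 fell with mannitol and 48 rose. The 2 contrasts share 3 control arrays, so numbers for independent sets are no measure of these counts. In 100 simulations with these shared arrays, independent genes and no mannitol effect, at most 5 rose and 2 fell among genes that fell with development. Among those that rose with development, at most 3 rose and 4 fell. Without a mannitol effect few genes can be called, so a mannitol effect in either direction can exceed these counts. The 48 rises and 5 falls that ran along development exceeded them too. The simulated counts therefore cannot tell whether the mannitol effect ran against development. The median mannitol change was 0.21 among genes that fell (simulated 0.0058 to 0.032) and -0.10 among genes that rose (simulated -0.042 to -0.0084). The correlation of the mature leaf effect with the step from expanding to mature control leaf was -0.29. Its covariance was -0.0414, against -0.00946 in simulations without a mannitol effect. The expanding leaf effect had r = -0.23 with the step from proliferating to expanding control leaf, which also shares 3 control arrays. The covariance there was -0.0780, against -0.00945 in the simulations. With arrays that are not shared, the expanding leaf effect had r = -0.13 with the change from proliferating to mature control leaf (covariance -0.0551, simulated -0.00058 to 0.00056). The mature leaf effect had r = -0.026 with the change from proliferating to expanding control leaf (covariance -0.0066, simulated -0.00052 to 0.00056).

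The 6 arrays of a stage can be split into 3 and 3 in 10 ways, so the share of splits with as many calls cannot fall under 0.1. It was 1 of 10 at every stage and for both development steps. The highest count of another split was 5 in seedlings, 46 in proliferating, 25 in expanding and 144 in mature leaf, and 1 and 24 for development. Among splits that part every pair of replicate numbers it was 0 in seedlings, 0 in proliferating and 5 in expanding leaf. It was 1 in mature leaf, where the pairing check did not pass.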
